A study of Homo sapiens with 12 samples.

How the data were processed

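Gene expression had been measured in U2OS cells, a human osteosarcoma line with wild-type p53 per the labels, on Affymetrix Human Genome U133 Plus 2.0 arrays. Total RNA had been amplified and marked with biotin with a 3' in vitro transcription kit, per the labels' protocols. There were 12 arrays in 4 groups of 3. Cells had been treated for 24 hours with 0.6 µg/ml doxorubicin or with 10 µM nutlin-3, and the controls were untreated cells for doxorubicin and cells in 0.1% DMSO for nutlin-3. The group and replicate number of each array were taken from its title. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

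The values came from the deposited series table, which holds 1 linear signal intensity per probe set and array. The authors made these intensity values with MAS5, per the submitters' processing notes, and no version or settings were used here. The mean signal after trimming 2% of the values at each end lay between 499.92 and 499.93 on every array, so the arrays share a common trimmed mean. Array medians lay between 79.6 and 113.6. The table holds 54675 probe sets, of which 62 are control probe sets. It was used without detection calls, so no probe set was called present or absent.

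Values were turned into log2(value + 16), so fold changes are on that scale and understate the change of dim genes. The between-array scaling of the authors was kept. Control probe sets were left out, as were probe sets whose mean lay under the 40th percentile, which corresponds to a signal of 49.3. The platform annotation gave 1 gene symbol for 41097 probe sets and several for 1801, and it did not list 11777. Symbols were updated through the gene identifier against the RefSeq gene table of assembly GRCh38.p14, and 13657 of the 13673 genes tested had a current symbol there. Each gene was represented by the probe set with the highest mean among those paired with exactly 1 symbol. Of 6970 genes with several probe sets past the filter, 201 had probe sets called in opposite directions with doxorubicin, 12 with nutlin-3 and 77 for the difference. The transcript of p53 itself was not analysed here.

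Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend. A single fit of all 12 arrays held 4 group means and no block. The contrasts were doxorubicin against untreated, nutlin-3 against DMSO, the difference of these 2 responses, and DMSO against untreated. A gene was called when its Benjamini-Hochberg adjusted p over the 13673 genes was under 0.05. Standard errors (SE) of log2 changes are those of limma's moderated fit. The comparisons of the agents share no control array, so overlaps of their calls were set beside the product of both list sizes divided by the genes tested. The number of arrays limits the precision of every value.

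A set of 23 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for the genes named. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 92 tests of 23 lists in 4 contrasts. An estimated correlation per list and fry were alternatives. Of the 92 tests, 29 passed with the preset correlation and 10 with the estimated one. Members were also adjusted over the list alone. An SE over members is the SD of the members' changes divided by the square root of their number. It treats members as independent, which they are not (estimated correlation 0.13 for DNA replication genes), and does not measure the spread between arrays. RNA quality was read from the 3' to 5' signal ratios of control probe sets and compared with exact 2-sided permutation tests, which cannot go below 0.1 with 3 arrays against 3.

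The rule named MDM2, MDM4, CDKN1A and TP73, and for each agent the 10 largest rises and 10 largest falls among called genes whose treated and control arrays did not overlap. Chance gives no overlap for 10% of genes with 3 arrays against 3. It also took, per agent and list, up to 2 called members with the largest rise and up to 2 with the largest fall. Not every gene that the rule took is reported here. For the difference it took the 8 largest in each direction, and for DMSO against untreated the 3 largest. *CCNG1* is also named with each agent because it was the only arrest target not called with doxorubicin, which was chosen after its values were seen. The same choice of list members was also applied to the difference between the agents. That step was not part of the rule fixed beforehand, and its results were kept in every table and alternative.

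Alternatives covered between-array scaling (quantile, median centring), pseudocounts of 1 and 64, no filter and a 60th percentile filter, other ways to choose probe sets, no trend, array weights, fits of 6 arrays, the replicate number as a block, each array left out, an adjusted p under 0.01, and a change of at least 2-fold. A further 3 were added after seeing the data. They kept only doxorubicin array 1, added the spike ratio as a covariate, or exchanged the controls.

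The procedure was tested on simulated data with known changes among 13673 genes. Only 66, 56 and 78 genes were changed 1.5-fold, 2-fold and 4-fold with doxorubicin, and 64, 73 and 63 with nutlin-3. The noise of each gene was drawn independently, and the control groups did not differ. The measured arrays had far more calls, correlated genes and differing controls, so the following shares need not hold for them. For doxorubicin against untreated, 60.6% of genes changed 1.5-fold were recovered, 78.6% of those changed 2-fold and 96.2% of those changed 4-fold, and 5.36% of the calls were false. For nutlin-3 against DMSO these shares were 48.4%, 76.7% and 92.1%, with 3.33% false calls.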

Results

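The series measured transcript levels in U2OS cells, a human osteosarcoma line that keeps wild-type p53. Doxorubicin, a topoisomerase II poison that breaks DNA, was compared with untreated cells. Nutlin-3, which blocks the binding of MDM2 to p53 without breaking DNA, was compared with its solvent DMSO. Each of the 4 groups had 3 arrays, taken after 24 hours. The design asks how the p53 response differs between the agents. Across genes, arrays of the same group correlated at 0.963 to 0.981, and 13673 genes were tested.

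Doxorubicin raised p53 target genes and lowered mitotic genes, together with very large changes outside these groups. *CDKN1A*, which encodes the cell cycle inhibitor p21, rose from a signal of 1361 ± 34.1 to 7678 ± 1114 (SD, n = 3), a log2 change of 2.47 (SE 0.11, adjusted p = 8.4e-12). *MDM2*, which encodes the ubiquitin ligase that restrains p53, rose by 1.42 (SE 0.07). *GDF15*, a secreted stress cytokine, rose by 5.46 (SE 0.22). In all, 7616 genes were called, 55.7% of those tested, of which 4112 were higher and 3504 lower with doxorubicin. *MDM4*, a relative of *MDM2*, had a log2 change of 0.02 (SE 0.10), and *TP73*, a relative of p53, had 0.36 (SE 0.27), neither past the threshold.

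Of the genes called with doxorubicin, 2257 changed at least 2-fold. *PADI4*, a peptidylarginine deiminase, rose from a signal of 14.6 ± 11.2 to 2966 ± 111 (SD, n = 3), a log2 change of 6.68. Its untreated signal lay under the filter signal of 49.3, and the change was 7.97 with a pseudocount of 1 and 5.28 with 64. The sizes for *GRHL3*, *RNASE7* and *SCEL* also depend on the pseudocount, since a group mean lay under that signal. *LRATD1* rose by 5.06, *TREM2*, a myeloid receptor, by 4.78 and *CSTA*, the protease inhibitor cystatin A, by 4.65. *AKR1B10*, an aldo-keto reductase, rose by 4.53, *GRHL3*, a transcription factor of epidermal differentiation, by 4.43, and *TSGA10* by 4.37. *SHISA2* rose by 4.30 and *RNASE7*, an antimicrobial ribonuclease of skin, by 4.23. *GPC6*, a cell surface glypican, fell from 5541 ± 264 to 311 ± 57.8 (SD, n = 3), a log2 change of -4.10. *TFPI*, an inhibitor of coagulation, fell by 3.92, *SCEL* fell by 3.81 and *BCAT1*, a branched-chain aminotransferase, fell by 3.74. *SHOC1*, *GPX8*, *WFDC21P*, *EFNB3*, *TENM2* and *ANXA10* had log2 changes of -3.46 to -3.62.

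**Figure D1:**
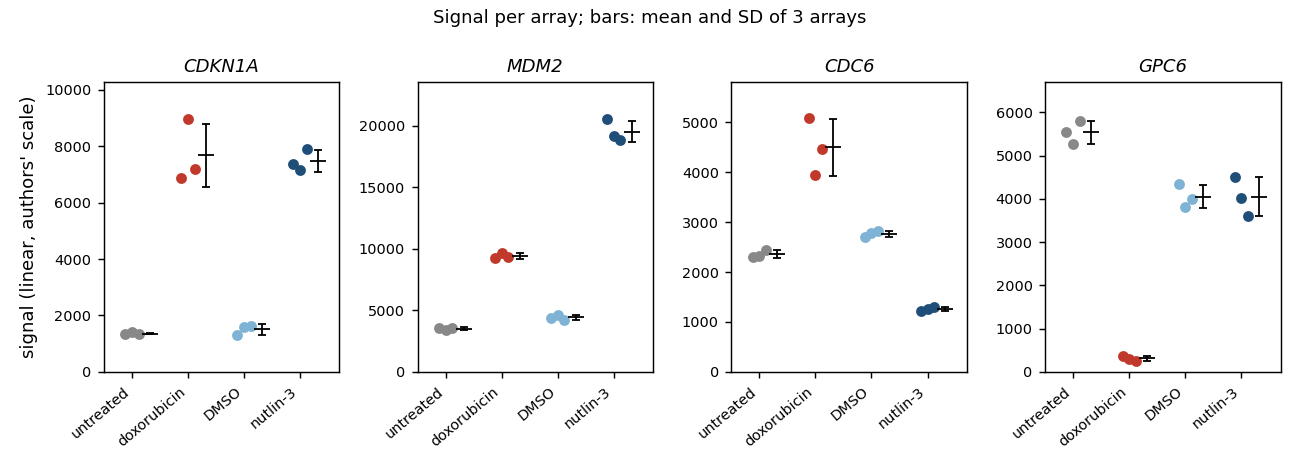
Signal per array (linear, authors' scale) of 4 genes in the 4 groups, with the mean and SD of 3 arrays beside the points. *CDKN1A* and *MDM2* were higher with both agents, *CDC6* was higher with doxorubicin (4495 against 2355) and lower with nutlin-3 (1255 against 2765), and *GPC6* was low with doxorubicin alone among the 4 groups (311).

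Among p53 targets in arrest and feedback, 20 of 21 measured members rose with doxorubicin and 0 fell, with a median log2 change of 1.79. The counts adjusted over the list alone were the same, and the list passed camera (adjusted p = 3.9e-11, and adjusted p = 0.010 with an estimated correlation). *TP53INP1* rose by 3.11 (SE 0.12). *CCNG1*, which encodes cyclin G1, had a change of -0.08 and did not pass. Of 16 p53 targets in apoptosis, 14 rose and 0 fell, and 15 rose when adjusted over the list alone (median 1.19, adjusted p = 7.9e-07, and adjusted p = 0.0079 with an estimated correlation). *TP53I3* rose by 3.06 (SE 0.07) and *FAS*, the death receptor, by 2.35 (SE 0.08). Of 11 targets in DNA repair and metabolism, 8 rose and 1 fell, also when adjusted over the list alone (median 1.16, adjusted p = 0.0044). This list did not pass with an estimated correlation (adjusted p = 0.069). *FUCA1*, a lysosomal fucosidase, rose by 3.51 (SE 0.09), *ACER2* by 3.34 (SE 0.18), and *LPIN1*, a phosphatidate phosphatase, fell by 0.86 (SE 0.13).

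Mitotic genes fell with doxorubicin. Of 35 measured members 31 fell and 2 rose, also when adjusted over the list alone, with a median log2 change of -0.84 (adjusted p = 3.6e-11, and adjusted p = 0.014 with an estimated correlation). The spindle checkpoint kinase gene *BUB1B* fell by 1.76 (SE 0.11) and *KIF20A*, a kinesin of cytokinesis, fell by 1.38 (SE 0.09). The members that rose were *CDK1*, the mitotic kinase gene, at 0.32 (SE 0.11) and *PTTG1*, which encodes securin, at 0.24 (SE 0.09). DNA replication genes went both ways, 9 of 39 rising and 15 falling (also when adjusted over the list alone), with a median of -0.08 (adjusted p = 0.28), which was -0.26 when arrays were centred on their medians. *CDC6*, a replication licensing gene, rose by 0.92 (SE 0.09) as did *CCNE1*, which encodes cyclin E1 (0.92, SE 0.09). *POLA1*, which encodes the catalytic subunit of polymerase alpha, fell by 1.96 (SE 0.16). Of 15 genes of homologous recombination and the Fanconi pathway, 4 rose and 4 fell (also when adjusted over the list alone), with a median of 0.04 a mean of -7.7e-05 and a test direction downwards (adjusted p = 0.73), and the median was -0.14 with arrays centred on their medians. *RMI1*, which acts with a helicase on recombination intermediates, rose by 0.31 (SE 0.10) and the checkpoint kinase gene *CHEK1* fell by 1.04 (SE 0.11). Of 11 histone genes 7 fell and 0 rose, also when adjusted over the list alone (median -0.55, adjusted p = 0.011). Histones did not pass with an estimated correlation (adjusted p = 0.56).

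Genes of antigen presentation, lysosomes and inflammation rose with doxorubicin at the preset correlation. Of 13 members of MHC class I antigen presentation 9 rose and 0 fell, with a median of 0.89 (adjusted p = 0.00088, but adjusted p = 0.22 with an estimated correlation). The peptide transporter gene *TAP1* rose by 3.33 (SE 0.10) and *HLA-C* by 1.19 (SE 0.10). Of 18 lysosome and autophagy genes 14 rose and 2 fell, with 15 rising when adjusted over the list alone (median 0.77, adjusted p = 0.0026, but adjusted p = 0.19 with an estimated correlation). *CTSL*, which encodes cathepsin L, rose by 1.83 (SE 0.11), *NEU1*, a sialidase, rose by 1.62 (SE 0.12), and *ATG10* fell by 1.69 (SE 0.15). With probe sets other than the _x_at and _s_at types where a gene had one, the lysosome list did not pass with doxorubicin (median 0.61, adjusted p = 0.052, range over the alternatives at the preset correlation 0.00090 to 0.052). Of 15 NF-kB targets 9 rose and 0 fell (median 0.99, adjusted p = 0.0053, but adjusted p = 0.22 with an estimated correlation), among them *PTGS2*, which encodes cyclooxygenase-2, at 2.07 (SE 0.27). Of 19 immediate early transcripts 15 rose and 2 fell (median 0.75, adjusted p = 0.0067, but adjusted p = 0.52 with an estimated correlation). *EGR1* rose by 2.42 (SE 0.24) and *MYC* fell by 0.49 (SE 0.13). Adjusted over the list alone, the counts for antigen presentation, NF-kB targets and immediate early transcripts were the same.

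Other lists held called genes in both directions with doxorubicin without passing as a list. Of 18 interferon-stimulated genes 8 rose and 4 fell (adjusted p = 0.50), with *ISG15*, a ubiquitin-like protein gene, rising by 2.74 (SE 0.10) and *IFIT1* at -1.82 (SE 0.17). Of 20 genes of ATF4 and the unfolded protein response 6 rose and 12 fell (median -0.60, adjusted p = 0.13). The transcription factor gene *ATF3* rose by 2.82 (SE 0.23), and the cystine transporter gene *SLC7A11* fell by 2.86 (SE 0.10) and the asparagine synthetase gene *ASNS* fell by 1.85 (SE 0.08). Of 15 NRF2 targets 10 rose and 2 fell (adjusted p = 0.058), with the malic enzyme gene *ME1* at -1.97 (SE 0.09). Of 12 genes of toll-like receptors, APOBEC3 and the inflammasome 6 rose and 1 fell (adjusted p = 0.058), with *TLR3* rising by 2.19 (SE 0.18). Of 18 cholesterol synthesis genes 1 rose and 11 fell (median -0.41, adjusted p = 0.089), with the reductase gene *DHCR7* at -1.78 (SE 0.17). Of 34 ribosomal protein genes 3 rose and 4 fell (adjusted p = 0.57), of 20 ribosome biogenesis genes 3 rose and 6 fell (adjusted p = 0.37). Of 16 matrix and osteoblast genes 4 rose and 7 fell (adjusted p = 0.50), and of 29 oxidative phosphorylation genes 13 rose and 8 fell (adjusted p = 0.87). Adjusted over the list alone, 11 NRF2 targets, 5 matrix and osteoblast genes and 14 oxidative phosphorylation genes rose, 2 ribosomal protein genes rose and 3 fell, and the counts of the other lists in this paragraph were the same. Among markers of other cell types, 3 of 5 leukocyte genes rose, with *LAPTM5*, a lysosomal membrane protein gene of blood cells, at 2.35 (SE 0.21). Of 4 epithelial genes 2 fell, and of 3 endothelial genes 1 fell, and none of these lists passed (adjusted p = 0.15, 0.35 and 0.70). The epithelial genes that fell, *KRT14* and *EPCAM*, did so only against untreated cells, and against DMSO their changes were 0.13 and 0.37. The endothelial list had a median of 0.21 and a mean of -0.24, with the test downwards.

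Of these lists 4 passed with doxorubicin in some settings at the preset correlation. The list of toll-like receptors, APOBEC3 and the inflammasome passed with median centring (adjusted p = 0.037), with no filter (adjusted p = 0.039), with the 60th percentile filter (adjusted p = 0.013), with the mean of all probe sets (adjusted p = 0.032) and without _x_at and _s_at probe sets where possible (adjusted p = 0.047). It also passed without untreated array 3 (adjusted p = 0.043) or DMSO array 2 (adjusted p = 0.044), and its range over the settings was 0.013 to 0.12. NRF2 targets passed with quantile normalization (adjusted p = 0.045), with no filter (adjusted p = 0.039), without untreated array 2 (adjusted p = 0.044) and without doxorubicin array 1 (adjusted p = 0.045), with a range of 0.039 to 0.12. The list of ATF4 and the unfolded protein response passed with no filter (adjusted p = 0.039) and without _x_at and _s_at probe sets where possible (adjusted p = 0.047), with a range of 0.039 to 0.25. Cholesterol synthesis passed with median centring (adjusted p = 0.043) and with no filter (adjusted p = 0.024), with a range of 0.024 to 0.21.

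Signs of RNA quality moved with doxorubicin and thus with each of these groups. The 3' to 5' signal ratio of *ACTB* was 3.12 ± 0.577 with doxorubicin and 1.53 ± 0.0754 in untreated cells (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 allows). The ratio of the spiked control dap was 7.67 ± 3.85 against 2.84 ± 0.401, and that of *GAPDH* was 1.07 ± 0.116 against 1.02 ± 0.0356. With only doxorubicin array 1, which had the lowest dap ratio of its group, 6356 genes were called. When each array was centred on its median, the median change of all genes moved from 0.08 to -0.10, and the share of calls that were higher moved from 54.0% to 38.4%.

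**Figure D2:**
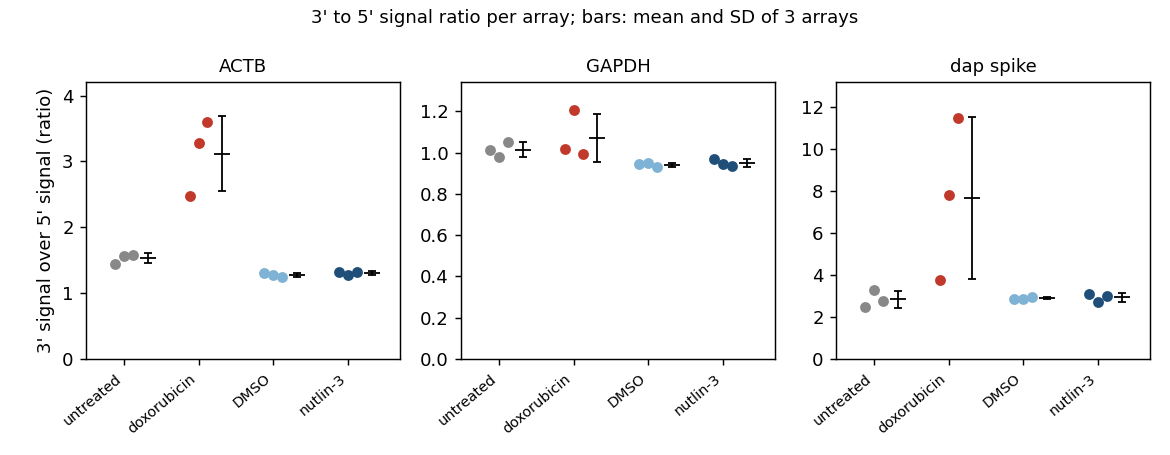
Ratio of 3' to 5' signal per array for *ACTB*, *GAPDH* and the spiked control dap, with the mean and SD of 3 arrays beside the points. The doxorubicin arrays reached 3.59 for *ACTB* and 11.5 for dap, while the highest dap ratio of the other 9 arrays was 3.27.

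Nutlin-3 raised the same kinds of p53 target and lowered genes of both mitosis and DNA replication. *CDKN1A* rose from a signal of 1507 ± 187 to 7470 ± 393 (SD, n = 3), a log2 change of 2.30 (SE 0.11, adjusted p = 1.9e-10). *MDM2* rose by 2.14 (SE 0.07) and *GDF15* by 3.55 (SE 0.22). In all, 3613 genes were called, 26.4% of those tested, of which 1713 were higher and 1900 lower, and 621 changed at least 2-fold. *MDM4* had a change of 0.01 (SE 0.10) and *TP73* of -0.18 (SE 0.27), neither past the threshold.

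With nutlin-3 *SUGCT*, a mitochondrial CoA transferase gene, rose from 448 ± 99.8 to 5596 ± 450 (SD, n = 3), a log2 change of 3.62. *SERPINB5*, which encodes maspin, rose by 3.58, *NBEAP1* by 3.55, *BCL2A1*, an anti-apoptotic BCL2 relative, by 3.51 and *ESM1*, a secreted proteoglycan, by 3.46. *PSTPIP2* rose by 3.10, *CSMD3* by 3.04, *LINC01088* by 3.00 and *UNC5B-AS1* by 2.94. The DMSO signals of *SERPINB5*, *NBEAP1*, *BCL2A1*, *ESM1* and *LINC01088* lay under the filter signal of 49.3, so their sizes and ranks depend on the pseudocount, and *SERPINB5* rose by 5.02 with a pseudocount of 1 and by 2.20 with 64. *LGR5*, a receptor for R-spondins, fell from 764 ± 127 to 104 ± 15.9 (SD, n = 3), a log2 change of -2.69. *FGF21*, a secreted metabolic hormone, fell by 2.19, and the changes were -2.17 for *ATOH8*, -2.01 for *INHBE*, -1.96 for *TNFAIP6* and -1.93 for *COL8A1*. *C1QTNF2*, *GPR19*, *PALM3* and *SOSTDC1* had log2 changes of -1.75 to -1.87, that of *SOSTDC1* with a treated signal under the filter signal.

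All 21 measured p53 targets in arrest and feedback rose with nutlin-3, with a median of 1.53 (adjusted p = 5.0e-24, and adjusted p = 0.0027 with an estimated correlation). *TP53INP1* rose by 2.51 (SE 0.12) and *CCNG1* by 0.95. Of 16 targets in apoptosis 12 rose and 0 fell, and 1 fell when adjusted over the list alone (median 1.16, and 0.75 with no filter, adjusted p = 2.0e-10). *CYFIP2* rose by 2.23 (SE 0.09) and *FAS* by 2.19 (SE 0.08). Of 11 targets in DNA repair and metabolism 7 rose and 0 fell, also when adjusted over the list alone (median 0.97, adjusted p = 7.2e-06), among them *RRM2B*, a p53-regulated ribonucleotide reductase subunit gene, at 1.65 (SE 0.11). With an estimated correlation these lists also passed (adjusted p = 0.0027 for apoptosis and adjusted p = 0.010 for DNA repair and metabolism).

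All 35 mitotic genes fell with nutlin-3, with a median of -0.91 (adjusted p = 8.5e-27, and adjusted p = 0.0027 with an estimated correlation). *KIF11*, a spindle kinesin, fell by 1.41 (SE 0.10) and the separase gene *ESPL1* fell by 1.32 (SE 0.08). Of 39 DNA replication genes 36 fell and 0 rose, with a median of -1.11 (adjusted p = 1.0e-26, and adjusted p = 0.010 with an estimated correlation). The E2F family genes *E2F8* and *E2F2* had changes of -1.64 (SE 0.10) and -1.61 (SE 0.14). Of 15 genes of homologous recombination and the Fanconi pathway 12 fell and 1 rose, with a median of -0.91 (adjusted p = 3.2e-09, and adjusted p = 0.0071 with an estimated correlation). *RAD54L* fell by 1.61 (SE 0.10) and *BRIP1*, a helicase gene, fell by 1.23 (SE 0.08). The counts of these 3 lists were the same when adjusted over the list alone.

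Smaller groups moved with nutlin-3 at the preset correlation. Of 15 NF-kB targets 6 rose and 0 fell (median 0.47, adjusted p = 0.00051, but adjusted p = 0.14 with an estimated correlation), led by the metalloproteinase gene *MMP3* at 1.89 (SE 0.12) and the chemokine gene *CCL20* at 1.65 (SE 0.21). Of 19 immediate early transcripts 13 rose and 0 fell (median 0.64, adjusted p = 4.3e-07, but adjusted p = 0.16 with an estimated correlation). Of 12 genes of toll-like receptors, APOBEC3 and the inflammasome 4 rose and 1 fell (adjusted p = 0.020, but adjusted p = 0.13 with an estimated correlation), with *APOBEC3C*, a cytidine deaminase, rising by 1.80 (SE 0.13). Of 11 histone genes 6 fell and 1 rose (median -0.30, adjusted p = 0.021, but adjusted p = 0.56 with an estimated correlation). Of 18 cholesterol synthesis genes 7 fell and 2 rose (median -0.28, adjusted p = 0.038, but adjusted p = 0.52 with an estimated correlation), with *INSIG1*, a regulator of sterol sensing, at -1.12 (SE 0.14). Of 34 ribosomal protein genes 7 rose and 0 fell (median 0.18, adjusted p = 0.00027, but adjusted p = 0.59 with an estimated correlation), and the median was 0.09 with quantile normalization (adjusted p = 0.018). The DMSO control itself differed from untreated cells the opposite way, with medians of -0.17 for ribosomal protein genes and 0.22 for cholesterol synthesis genes. These nutlin-3 changes thus depend on the choice of control. The histone list did not pass without DMSO array 2 (median -0.24, adjusted p = 0.061) or without nutlin-3 array 1 (median -0.18, adjusted p = 0.082). The cholesterol list did not pass without DMSO array 1 (median -0.24, adjusted p = 0.078), nutlin-3 array 2 (median -0.15, adjusted p = 0.086) or nutlin-3 array 3 (median -0.31, adjusted p = 0.067), with the 60th percentile filter (median -0.26, adjusted p = 0.062) or with the mean of all probe sets (median -0.19, adjusted p = 0.068). Over the alternatives at the preset correlation the adjusted p ranged from 0.0064 to 0.082 for histones, from 0.011 to 0.086 for cholesterol synthesis and from 0.0043 to 0.087 for toll-like receptors, APOBEC3 and the inflammasome, whose list did not pass without a filter (median 0.22 against 0.49, adjusted p = 0.087) or with the 60th percentile filter (adjusted p = 0.066). Adjusted over the list alone, 7 NF-kB targets, 15 immediate early transcripts, 6 genes of the toll-like receptor list and 5 ribosomal protein genes rose, 8 cholesterol synthesis genes fell, and the histone counts were the same.

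The remaining lists did not pass with nutlin-3. Of 13 genes of MHC class I antigen presentation 3 rose and 0 fell (adjusted p = 0.36), with *TAP1* at 1.63 (SE 0.10). Of 18 interferon-stimulated genes 2 rose and 6 fell (adjusted p = 0.11), and *ISG15* rose by 0.43 (SE 0.10). Of 20 genes of ATF4 and the unfolded protein response 3 rose and 2 fell (adjusted p = 0.99), and *SLC7A11* fell by 0.63 (SE 0.10). Of 18 lysosome and autophagy genes 5 rose and 1 fell (adjusted p = 0.22). Of 15 NRF2 targets 5 rose and 1 fell (adjusted p = 0.078), of 20 ribosome biogenesis genes 3 rose and 1 fell (adjusted p = 0.21), and of 29 oxidative phosphorylation genes 7 rose and 0 fell (adjusted p = 0.089). Of 16 matrix and osteoblast genes 3 rose and 4 fell (adjusted p = 0.82), whose median was 0.07 and mean -0.10 with the test downwards, with *COL6A3* rising by 1.21 (SE 0.11) and *COL3A1* at -1.54 (SE 0.11). Of the markers of other cell types, 1 of 5 leukocyte genes rose, 1 of 4 epithelial genes fell and 0 of 3 endothelial genes changed (adjusted p = 0.36, 0.44 and 0.99). The endothelial list had a median of 0.05 with the test downwards. Adjusted over the list alone, 7 interferon-stimulated genes fell and 6 lysosome and autophagy genes rose, and the counts of the other lists in this paragraph were the same. NRF2 targets passed with no filter (adjusted p = 0.039) and without DMSO array 3 (adjusted p = 0.045), with a range of 0.039 to 0.17 over the settings at the preset correlation, and oxidative phosphorylation passed without nutlin-3 array 1 (adjusted p = 0.040, range 0.040 to 0.31). The *ACTB* ratio was 1.31 ± 0.0260 with nutlin-3 and 1.28 ± 0.0281 with DMSO (SD, n = 3, exact permutation p = 0.2).

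**Figure D3:**
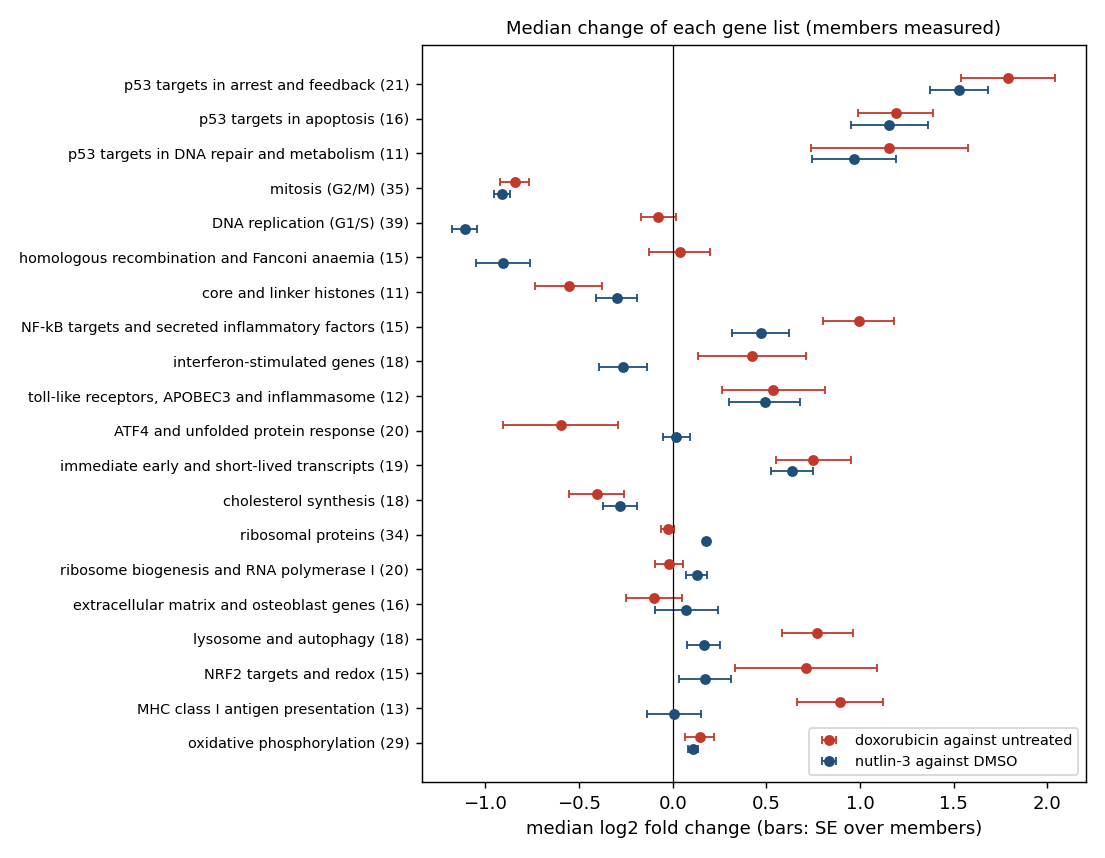
Median log2 fold change of the measured members of 20 gene lists with doxorubicin against untreated cells and nutlin-3 against DMSO, with the SE over members. Both agents gave medians of 1.79 and 1.53 for p53 targets in arrest and feedback, while DNA replication genes had medians of -0.08 with doxorubicin and -1.11 with nutlin-3.

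Both agents shared many calls in the same direction. Among genes raised by nutlin-3, 1128 were also raised by doxorubicin, where independent lists of these sizes would share 515.2. Among genes lowered by nutlin-3, 1013 were also lowered by doxorubicin, where independent lists would share 486.9. These are 65.8% of the rises and 53.3% of the falls with nutlin-3. A further 304 genes were higher with doxorubicin and lower with nutlin-3, and 190 the other way around, where independent lists would give 571.4 and 439.0. Across genes, which are not independent replicates, the fold changes of the agents correlated with Pearson's r = 0.436 and Spearman's rho = 0.344.

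**Figure D4:**
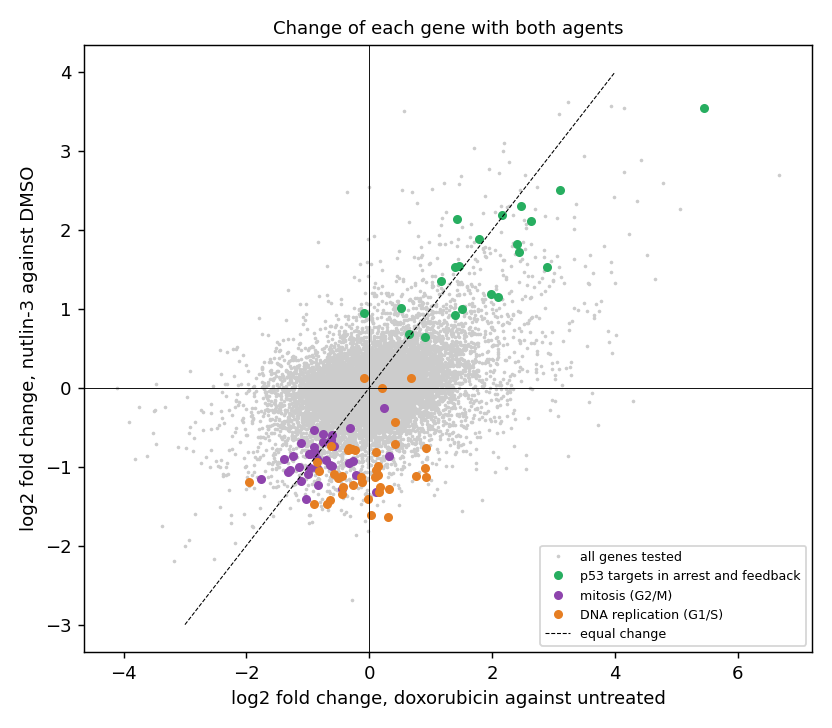
Log2 fold change of each of 13673 genes with doxorubicin (horizontal axis) and with nutlin-3 (vertical axis), with 3 gene lists in colour and a dashed line of equal change. Genes of p53 targets in arrest and feedback lie at positive nutlin-3 values (median 1.53), mitotic genes are low on both axes (medians -0.84 and -0.91), and replication genes are low on the nutlin-3 axis only as a group (medians -0.08 and -1.11).

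The difference between the responses was also tested directly, and it included genes of DNA synthesis. Of 39 DNA replication genes 33 had a higher change with doxorubicin than with nutlin-3 and 1 a lower one, with a median difference of 0.90 (adjusted p = 2.7e-11, but adjusted p = 0.069 with an estimated correlation). *CDC6* differed by 2.05 (SE 0.13), *E2F8* by 1.95 (SE 0.15) and *POLA1* by -0.77 (SE 0.23). Of 15 genes of homologous recombination and the Fanconi pathway 11 had the higher change with doxorubicin and 0 the lower (median difference 0.82, adjusted p = 2.7e-05, and adjusted p = 0.020 with an estimated correlation), among them *RAD54L* at 1.91 (SE 0.13). Mitotic genes as a list did not differ past the threshold (median difference 0.06, adjusted p = 0.69, and -0.09 with arrays centred on their medians). Of the lists, 18 did not pass the test of a difference (lowest adjusted p = 0.089), and among these the immediate early transcripts had a median of 0.13 with the test downwards. Of these 18, ATF4 and the unfolded protein response passed with no filter (adjusted p = 0.032, range 0.029 to 0.20) and without _x_at and _s_at probe sets where possible (adjusted p = 0.029), ribosome biogenesis passed with no filter (adjusted p = 0.029, range 0.029 to 0.19), and histones passed with the spike ratio as a covariate (adjusted p = 0.047, range 0.047 to 0.25). In all, 5396 genes differed between the responses, 2982 with the higher change in doxorubicin and 2414 with the lower, and 1828 by at least 2-fold.

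The p53 target lists did not pass camera's test of a difference (adjusted p = 0.36, 0.37 and 0.36 for arrest and feedback, apoptosis, and DNA repair and metabolism). In the same order, 10 of 21, 6 of 16 and 3 of 11 members had a higher change with doxorubicin, and 3, 2 and 1 a lower one. Of all genes tested, 39.5% differed. With fry, which does not compare a list with other genes, these lists passed (fry adjusted p = 0.016, 0.00011 and 0.00037). *MDM2* rose less with doxorubicin, by -0.72 (SE 0.10, adjusted p = 3.0e-05). *CCNG1* differed by -1.03 (SE 0.13) and *BAX*, a pore-forming apoptosis gene, by -0.66 (SE 0.14). *GDF15* differed by 1.91 (SE 0.31), *PLK3* by 1.37 (SE 0.27) and *FUCA1* by 1.97 (SE 0.13). The difference of *CDKN1A* was 0.17 (SE 0.15, adjusted p = 0.40).

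Outside the p53 lists, the largest positive differences at the pseudocount of 16 were those of *SHISA2* at 4.46, *ALPP*, a placental alkaline phosphatase, at 4.19, *CA2*, a carbonic anhydrase, at 4.10 and *PADI4* at 3.98. *CRISPLD2*, *ADCYAP1R1*, *CCM2L* and *CRTAC1* differed by 3.52 to 3.76. The signals of *ALPP*, *PADI4* and *CRTAC1* lay under the filter signal in at least 1 control group, so their sizes and ranks depend on the pseudocount. The largest negative differences were those of *GPC6* at -4.10, *TENM2*, a synaptic adhesion gene, at -3.52, *BCAT1* at -3.50 and *TFPI* at -3.49. *WFDC21P* differed by -3.22, *EFNB3* by -3.21, *NEGR1* by -3.13 and *INPP4B* by -3.08. Genes of MHC class I antigen presentation differed upwards in 10 of 13 members (11 when adjusted over the list alone), with a median of 0.91 (adjusted p = 0.00091, but adjusted p = 0.22 with an estimated correlation), which was 0.56 with exchanged controls. Lysosome and autophagy genes differed upwards in 11 of 18 and downwards in 3 (median 0.60, adjusted p = 0.021, but adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes differed downwards in 8 of 34 (5 when adjusted over the list alone, median -0.20, adjusted p = 0.0054, but adjusted p = 0.68 with an estimated correlation), and their median difference was -0.10 with quantile normalization, -0.36 with median centring, -0.32 with doxorubicin array 1 alone, -0.34 with the spike ratio as a covariate and 0.08 when the controls were exchanged.

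The *ACTB* ratio of the doxorubicin arrays was 2.39 times that of the nutlin-3 arrays, so it moved with these differences as well. With only doxorubicin array 1, 4736 genes differed, and the share of differences that were positive moved from 55.3% to 39.6% when arrays were centred on their medians, with the median of all genes moving from 0.07 to -0.08. The lysosome list did not pass with the spike ratio as a covariate (adjusted p = 0.075), with the mean of all probe sets (adjusted p = 0.067) or without _x_at and _s_at probe sets where possible (adjusted p = 0.12), and the range over the alternatives at the preset correlation was 0.011 to 0.12.

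The control groups also differed. Between DMSO and untreated cells 1930 genes were called, 14.1% of those tested, of which 1113 were higher and 817 lower in DMSO, and 153 changed at least 2-fold. *FRG2EP* was higher in DMSO by 2.13 (SE 0.18), *ART5* by 1.87 (SE 0.38) and *EEF2KMT* by 1.78 (SE 0.28), the latter pair from untreated signals under the filter signal. *SOSTDC1*, a secreted BMP and Wnt antagonist, was lower at -2.33 (SE 0.38), as was *SLITRK6* at -2.24 (SE 0.22). The receptor kinase gene *ROR1* was lower, at a signal of 259 ± 30.8 in DMSO against 1099.5 ± 263 (SD, n = 3). Ribosomal protein genes had a median of -0.17 (adjusted p = 3.8e-05, but adjusted p = 0.57 with an estimated correlation), with 0 rising and 3 falling of 34 (13 when adjusted over the list alone). Cholesterol synthesis genes had a median of 0.22 (adjusted p = 0.036, but adjusted p = 0.52 with an estimated correlation), with 3 rising and 0 falling of 18 (7 rising when adjusted over the list alone). Epithelial markers fell in 2 of 4, with a median of -0.46 (adjusted p = 0.0097, but adjusted p = 0.11 with an estimated correlation).

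The 18S control signal was 16868 ± 1306 in untreated cells and 4878 ± 339 in DMSO (SD, n = 3, exact permutation p = 0.1, the smallest possible). Without untreated array 1 the count of genes that differed between the controls was 1236, without DMSO array 2 it was 1185 and without DMSO array 3 it was 1100. Centring the arrays on their medians moved the median of all genes from 0.02 to 0.15 and the share of higher calls from 57.7% to 80.3%.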

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

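The tests of the *ACTB* ratio (dap and *GAPDH*) and of separate preparation (18S, 28S and Alu) were chosen only after their values were seen. The settings with doxorubicin array 1 alone, with the spike ratio as a covariate and with exchanged controls were chosen after seeing the data.

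DNA replication genes differed between the agents by a median of 0.90 on the log2 scale, with the test of the difference passing at the preset correlation (adjusted p = 2.7e-11) but not with an estimated one (adjusted p = 0.069). Scaling between arrays is a candidate explanation, but quantile normalization gave 0.93 (SE over members 0.10). Median centring gave 0.74, so the scaling changed the size of this difference but not its direction. A bias of the labelling reaction of doxorubicin arrays 2 and 3 is another, but array 1 alone gave 0.88 (SE 0.11). With exchanged controls the median difference was 0.66 (SE 0.09). With the spike ratio as a covariate this difference still passed at the preset correlation, so a trend with the dap ratio does not by itself remove the call. The agents themselves remain an open explanation as a hypothesis, since doxorubicin array 1 also had a raised dap ratio and each agent has a control of its own.

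The *ACTB* 3' to 5' ratio with doxorubicin, 3.12, lay above those of the control arrays, as did the dap spike ratio at 7.67. A labelling reaction that worked less well may account for part of it, since the lowest dap ratio of a doxorubicin array, 3.76, lay above the highest of the other 9 arrays, 3.27, and spiked RNA does not come from the cells. The *GAPDH* ratio with doxorubicin was 1.06 times that of untreated cells and 1.13 times that of nutlin-3, and it reached 1.21 on doxorubicin array 2. The dap ratio was 2.70 times that of untreated cells while *GAPDH* hardly moved. A nearly flat *GAPDH* ratio therefore cannot tell general RNA degradation from labelling, and degradation stays open. An effect of doxorubicin on the *ACTB* transcript stays open and was not tested.

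The 18S signal of untreated cells, 16868, was 3.46 times that of DMSO, and doxorubicin was 1.76 times nutlin-3. The 28S signal followed this only for the controls (1.43 times, and 0.984 times for doxorubicin over nutlin-3). The Alu control signal followed it in both (1.33 times for untreated over DMSO and 1.41 times for doxorubicin over nutlin-3). A separate preparation of the pairs may account for some of the 1930 genes that differed between the controls, and it cannot be told apart from the solvent, because no group has one without the other. Within the pairs, the 18S signal with doxorubicin was 0.507 times that of untreated cells and that with nutlin-3 was 0.999 times that of DMSO, so subtracting each agent's own control does not remove this difference from the comparison of the responses.

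The responses differed in 5396 genes by the test of the difference, and 304 genes were higher with doxorubicin and lower with nutlin-3, with 190 the other way around. Genes of homologous recombination differed by a median of 0.82, of antigen presentation by 0.91, of lysosomes by 0.60 and ribosomal protein genes by -0.20, each past the threshold at the preset correlation. With an estimated correlation homologous recombination passed (adjusted p = 0.020), and antigen presentation (adjusted p = 0.22), lysosomes (adjusted p = 0.31) and ribosomal proteins (adjusted p = 0.68) did not. The ribosomal median was 0.08 with exchanged controls.

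Other groupings of the arrays were also counted. For doxorubicin 1 of the 10 splits of the 6 arrays gave as many genes (7616, and the highest other gave 1), and the same held for nutlin-3 (3613 and 0) and for DMSO against untreated (1930 and 0). These splits are too few for a share under 0.05. Of 100 groupings of the 12 arrays, 1 gave as many genes whose response differed (5396, highest other 4213) and 1 gave as many shared calls (2141, highest other 1), so a random assignment of the arrays to the groups can be excluded for both counts. Groupings that mix arrays of unlike groups widen the spread within groups, and 91 of the other 99 gave 0 differences and 98 gave 0 shared calls, so these counts do not show whether the overlap exceeds what unrelated responses would give. Another 7 groupings gave 2251 to 4213 differences, and the cause was not tested. As many list calls as observed (29) came from 39 of the 100 groupings, with up to 54. Groupings that mix treated and control arrays unevenly can still carry effects of the agents into list calls. Chance is thus not excluded for the number of list calls at the preset correlation, but this count does not show how many calls are false. It says nothing about any single list.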

How the results depend on the processing

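The alternatives that kept doxorubicin array 1 alone, used the spike ratio or exchanged the controls were chosen after seeing the data. Of 69 list results in the agents and their difference, 54 stayed on their side of the threshold in every setting run at the preset correlation, and 44 did so with the estimated correlation included. In these settings 20 list results changed the sign of their median, none of them a called one, while with exchanged controls the called difference of ribosomal protein genes went from -0.20 to 0.08. Over the settings at the preset correlation 18 list calls were lost and 22 gained. Of 268 gene results, 168 stayed on their side of the threshold without a called gene changing direction in every setting run, and 356 gene calls were lost over the settings. Where a count moved by over 1.5 times, the alternatives were the following. Testing every probe set gave 13182 for doxorubicin, 8679 for the difference and 3760 for DMSO against untreated, because more features were tested. An adjusted p under 0.01 gave 2327 for nutlin-3, 832 for DMSO against untreated and 1397 shared calls, and a change of at least 2-fold gave 2257 for doxorubicin, 621 for nutlin-3, 1828 for the difference, 153 for DMSO against untreated and 325 shared calls, both by their stricter rule. The list calls went from 29 to 10 with an estimated correlation (19 lost and 0 gained) and to 58 with fry (2 lost and 31 gained), which tests a list without comparing it with other genes. With exchanged controls nutlin-3 was compared with untreated cells and gave 5432, which includes the difference between the control groups. What caused that difference was not tested. Leaving out each array in turn gave 1100 to 2091 genes for DMSO against untreated. With doxorubicin array 1 alone, which assumes that it varies like the other groups, 6356 genes were called for doxorubicin, 4736 for the difference and 1959 shared calls. The spike ratio as a covariate gave 5434 for doxorubicin and 4040 for the difference.

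The direction of 13 gene results reversed, and 9 of these are differences between the agents taken by the added choice of list members. Without _x_at and _s_at probe sets where possible, *IFI44* had a difference of 0.17. With exchanged controls the change with doxorubicin was 0.061 for *UTP20*, -0.058 for *COL5A1*, 0.13 for *KRT14* and 0.37 for *EPCAM*. In the same setting the difference was -0.067 for *PIDD1*, -0.34 for *H2BC11*, -0.16 for *PTGS2*, -0.26 for *EBP*, -0.19 for *HSD17B7*, -0.094 for *NOP58*, 0.51 for *UTP20* and 2.03 for *KRT14*. Exchanging the controls shifts these values by way of the difference between DMSO and untreated cells (-1.79 for *KRT14* and 0.67 for *COL5A1*). The reversals with exchanged controls therefore come from that difference, whose own cause was not tested. The cause of the reversal of *IFI44* was not tested either.

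With the replicate number as a block, 7824 genes were called for doxorubicin, 3896 for nutlin-3, 5688 for the difference, 2279 for DMSO against untreated, 2309 shared calls and 29 list calls, and no call of a named gene or list changed. Arrays with the same number had deviations that correlated at -0.089 to 0.172, and 4 of 12 arrays correlated best with their own number. No clear pairing by number was seen. A small shared effect is not excluded, since each gene count was higher with the block than without it. Lists were not run on 6 arrays, on every probe set, at 2-fold or with exchanged controls as tests. Signal over background was not known, as no detection calls were used, so changes of dim genes are the least precise.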

Other observations

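Both lists in this part, very long genes and epidermal differentiation genes, were chosen after seeing the data, as were the settings with the spike ratio and with doxorubicin array 1 alone, and each list was written before its own test. Very long genes were listed from general knowledge because several of the largest falls with doxorubicin, such as *GPC6* and *TENM2*, are long genes, and neither of these is on the list. Of 61 measured members 1, *COL5A1*, is a named gene and was left out. Of 60 such genes 43 fell with doxorubicin and 9 rose, with a median of -0.97, below the central 95% of 10000 random lists matched on mean signal (-0.10 to 0.31). With nutlin-3 the median was -0.0025, 12 fell and 6 rose, and the median lay within the random range (-0.11 to 0.10), although its SE over members (0.07) does not exclude a fall past that range. In the test of the difference between the agents 39 were lower and 3 higher, with a median of -0.90 (adjusted p = 7.2e-10, and adjusted p = 0.00024 with an estimated correlation). The *ACTB* 3' to 5' ratio (3.12 against 1.53) and the dap ratio (7.67 against 2.84) also moved with doxorubicin. With the dap ratio as a covariate the median was -0.78 (SE over members 0.14, 33 fell and 6 rose, random lists -0.10 to 0.36), and with doxorubicin array 1 alone it was -0.96 (SE 0.13, 37 fell and 7 rose, random lists -0.11 to 0.33), which argues against the trend with the dap ratio, or a bias of arrays 2 and 3, as the whole cause. Other effects of labelling shared by all 3 doxorubicin arrays stay open. Another candidate explanation is that a DNA-bound topoisomerase poison hinders transcription over long distances, which was not tested, and gene length was not measured here.

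Several of the largest rises with doxorubicin, such as *CSTA*, *GRHL3* and *RNASE7*, are known from differentiating epidermis. *SCEL*, also known from that tissue, was among the largest falls, at a log2 change of -3.81 that depends on the pseudocount. The list tested here does not hold *SCEL*, so its values leave out this fall. A list of epidermal differentiation genes, written after these rises were seen, lay within the random range once the 5 named genes among its 35 measured members were left out. Its median was 0.43 with doxorubicin, within the random range of -0.08 to 0.46, and 0.12 with nutlin-3, within -0.13 to 0.18. These lie at the 96.1 and 90.7 percentiles of the random lists, with SEs over members of 0.26 and 0.12, so a general rise of epidermal genes was neither shown nor excluded. With doxorubicin 13 of the 30 rose and 5 fell, the falls including *KRT75* at -2.17 (SE 0.12) and *TGM1* at -1.72 (SE 0.32). *KRT75* was also lower in DMSO than in untreated cells, at -1.34 (SE 0.12), while *TGM1* had -0.02 there. Over all 35 measured members, the named ones included, 17 rose and 6 fell with a median of 0.54.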
